A study of Mus musculus with 6 samples.

How the data were processed

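Interscapular brown fat of control and Olfm4CKO mice was profiled by RNA sequencing, with 3 libraries per group by the genotype label. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a kit for messenger RNA. Reads were trimmed with cutadapt 1.11, aligned with HISAT2 2.1.0 and counted with featureCounts 1.6.0 on mm10, per the submitters' processing notes. The gene annotation and the strand setting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes may be shared. The deposited table is named for FPKM, but every value is a whole number and columns sum to different totals between 12108535 and 17309325, so the values were taken as raw read counts per gene, as deposited.

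The table has 35978 rows, of which 35975 carry counts for replicates 1 and 2 of both groups. The row of Neb is broken over 3 lines without counts and was left out. In 27 rows a spreadsheet had turned the symbol into a date, and these were counted but not named. The replicate 3 columns are filled from the top for 24276 rows and blank for 11702. Their values do not follow the printed gene names, as the rank correlations in the results show, and no gene was assigned to them by row order. They were left out of every comparison per gene. All 6 columns were matched to samples by name. Symbols were looked up in the RefSeq gene table of GRCm38.p6, the assembly of mm10, which held 33478 of the named rows, and coordinates are 1-based from that table. Transcript lengths came from GENCODE vM21.

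The comparison between Olfm4CKO and Ctrl used 2 libraries per group in edgeR 4.0.16 under R 4.3.3: filterByExpr (minimum count 10, minimum total 15), TMM scaling, quasi-likelihood fit on group, and Benjamini-Hochberg adjustment with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. The design written before the data were examined assumed FPKM from 6 libraries with a limma fit and a filter on mean FPKM, and named edgeR if the values proved to be counts. The use of 4 libraries and of filterByExpr departs from it. Group values are normalised CPM, mean ± SD. With 2 libraries against 2, an exact two-sided permutation test cannot go below 0.333, so none was run for the difference between groups in a gene. The exact interval of a count ratio and the limit for a count of 0, which is 3 counts of the total, cover counting error only. The 95% intervals of fold changes come from the quasi-likelihood fit and include the spread between libraries.

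In all, 48 gene lists were fixed before the data were examined, and 998 of their 1009 symbols matched a row. Lists with at least 3 tested members, 46 in number, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 46 lists. Camera compares a list with all other genes. Named genes follow a rule fixed at the same time: Olfm4, the 10 smallest p where fewer than 5 genes pass, up to 4 members with the smallest p of each list past the camera threshold, and 21 genes named in advance for brown fat, nerve and other cell types. The rule leaves out predicted genes and pseudogenes, and 3 such rows were passed over among the smallest p. Besides Olfm4, which had too few counts to be tested, it gave 88 genes, of which 87 were tested. Of these, 3 are not reported here, though they stayed in every fit and list. Named outside the rule, after their values were seen, were Cyp2e1, Elmod2, Tbc1d9, Xist, Y-linked genes, clock genes, genes called when libraries were split by replicate number, and genes called under an alternative.

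Replicates 1 and 2 of a group differed by far more than counting noise (chi-square per degree of freedom 85.2 in Ctrl and 130.1 in Olfm4CKO), so no library was counted as a duplicate. The pipeline was tested on simulated counts with 200 changed genes for this comparison of 2 against 2 libraries. At the dispersion of these libraries it recovered 10% of 2-fold and 99% of 8-fold changes among 13312 genes, with 7 false calls of 116. At a much lower dispersion (0.0116 against 0.1164) it recovered 98% and 100% among 13388 genes. The simulation gave genes of the same level the same dispersion and held no differences shared across genes within a library. It changed only genes with enough counts, and the 8-fold changes ease the adjustment for the 2-fold ones. The share recovered in the real libraries can therefore be lower. Alternatives covered the filter, the scaling, the variance model, DESeq2 1.42.0, limma-voom, each library left out in turn and the replicate number as a block.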

Results

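Messenger RNA was sequenced from the interscapular brown fat of C57BL/6 mice, the depot between the shoulder blades that produces heat. The labels give 3 control libraries (Ctrl) and 3 libraries from mice in which Cre recombinase, driven by the brown adipocyte gene Ucp1, deletes floxed Olfm4 (Olfm4CKO). They do not say whether controls carry the Cre transgene, so a difference between the groups can be one of Cre as well as of Olfm4. Olfm4 encodes olfactomedin 4, a secreted glycoprotein. The comparison asks how the transcripts of the depot differ between these groups, within a series whose title is about Schwann cells, innervation and the MEK/ERK pathway. Total counts were 15953676 and 17309325 in Ctrl replicates 1 and 2 and 15547569 and 15346705 in Olfm4CKO replicates 1 and 2. The replicate 3 columns held 12108535 (Ctrl) and 12470249 (Olfm4CKO) counts, but their rows did not match the gene names beside them. Their Spearman correlation with the other 4 libraries lay between -0.0209 and -0.0156 across rows, against 0.9677 with each other and 0.94 to 0.9474 among the other 4. Every value per gene below therefore comes from 2 Ctrl and 2 Olfm4CKO libraries. Nothing in the labels says that the libraries came from separate mice, so p-values measure the spread between these libraries only.

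**Figure D1:**
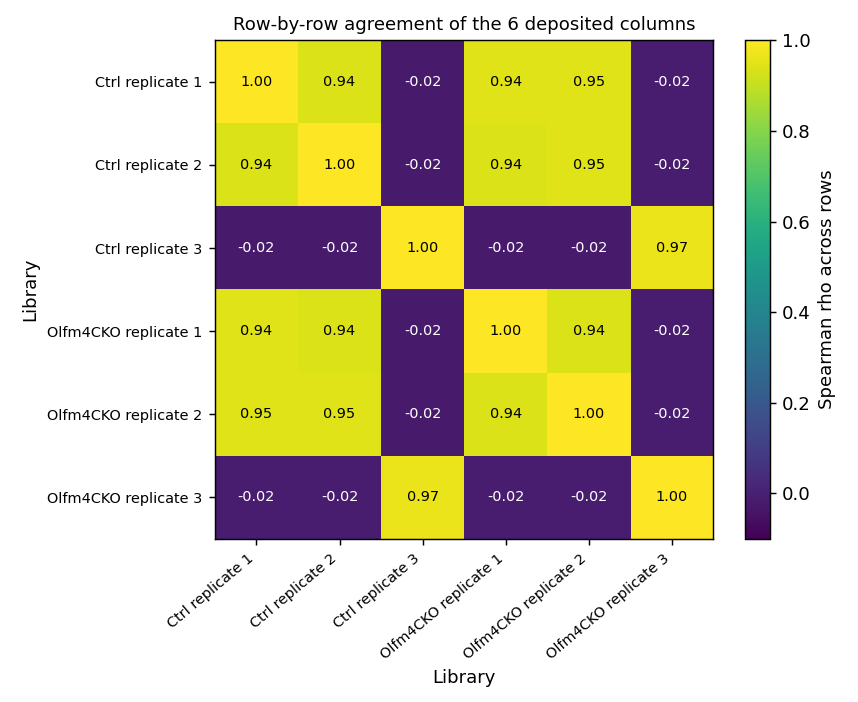
Spearman correlation across rows between each pair of the 6 deposited columns, with the library on both axes and the coefficient printed in each cell. The 4 columns of replicates 1 and 2 correlate at 0.94 or above with each other, and the replicate 3 columns correlate only with each other.

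Olfm4, the targeted gene, had 0 counts in all 4 libraries with matching rows, the controls included. A count of 0 allows up to 0.188 and 0.173 CPM in Ctrl replicates 1 and 2 and up to 0.193 and 0.195 CPM in Olfm4CKO replicates 1 and 2, or 0.09 CPM over both Ctrl libraries, counting error only. Loss of the transcript was not detectable at this depth, and the gene cannot check the genotype labels. The titles of the knockout samples also carry a wild-type tag for Olfm4, so groups follow the genotype field. Of the other genes with an olfactomedin domain, 10 were tested, with a median log2 fold change of 0.14 and did not pass as a list (camera adjusted p = 0.465).

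No gene passed edgeR's threshold between Olfm4CKO and Ctrl in the fit on group alone. Of 13573 genes tested with edgeR's quasi-likelihood test, 0 had a Benjamini-Hochberg adjusted p below 0.05 and the smallest was 0.9998. At an unadjusted p below 0.05 there were 287 genes, 204 higher and 83 lower in Olfm4CKO, where chance alone gives 679. The groups did not overlap for 24.63% of genes, against 33.3% by chance. DESeq2 called 1 gene, Cyp2b10, and limma-voom 0. With the replicate number as a block, edgeR called 4 genes, Cyp2b10 among them. The spread between libraries of a group was wide, with a biological coefficient of variation of 32.6%. The median half-width of the 95% interval was 0.89 on the log2 scale. In simulated counts at this dispersion 10% of 2-fold changes were recovered. The simulation was simpler than these libraries, so the share here can be lower. The count depended on single libraries: 25 genes passed without Ctrl replicate 1, among them Prx, Epn3 and muscle genes, 27 without Ctrl replicate 2 and 27 without Olfm4CKO replicate 1, each with Xist and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty among them, and 6 without Olfm4CKO replicate 2, where the lone library of a group is assumed to vary like the other group. Of the 84 tested genes that the naming rule gave and that are reported here, 65 had a log2 fold change that moved by over 1.5 times or changed sign when 1 library was left out, and 11 passed in at least 1 of those fits.

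The genes with the smallest p did not pass in edgeR's fit on group alone either. Cyp2b10, a cytochrome P450 induced by the nuclear receptor CAR (chromosome 7, 25897658 to 25926624, GRCm38), had 41.3 ± 34.8 CPM in Ctrl and 6.06 ± 0.382 CPM in Olfm4CKO (mean ± SD, n = 2 each, as for all group values). Its log2 fold change was -2.77 with a standard error of 0.56 (edgeR adjusted p = 0.9998), and DESeq2 called it (adjusted p = 0.00923). Ctrl replicate 1, the library with Y-linked transcripts, had 65.9 CPM and Ctrl replicate 2 16.7 CPM. The log2 fold change was -1.47 without the former (edgeR adjusted p = 0.623) and -3.43 without the latter (4.44e-09), and the gene also passed without Olfm4CKO replicate 1 (1.50e-04) but not without Olfm4CKO replicate 2 (0.210). A lower value was also seen for the myelin gene Mbp. Higher in Olfm4CKO were the transcription factors Bcl6b (log2 fold change 1.63) and Tbx3 (1.45), the glutamine transporter Slc38a3 (2.94), the lysosomal gene Litaf (1.38), the fibronectin receptor subunit Itga5 (1.30), the scaffold gene Akap12 (1.43) and the endocytic adaptor Epn3 (3.19). Epn3 had 9.43 and 1.84 CPM in Olfm4CKO replicates 1 and 2, with a log2 fold change of 1.599 without the former, and it passed without Ctrl replicate 1 (edgeR adjusted p = 0.0250) and without Olfm4CKO replicate 2 (0.0338; range over the libraries left out 0.0250 to 1.00). Bcl6b passed without Olfm4CKO replicate 1 alone (edgeR adjusted p = 0.0213; range 0.0213 to 0.884). Tbx3 went from 19.5 ± 2.22 to 53.3 ± 10.4 CPM and Itga5 from 14.6 ± 0.470 to 36.0 ± 0.161 CPM. The fold change of Slc38a3 rests on few counts, 6 and 4 in Ctrl replicates 1 and 2 and 33 and 42 in Olfm4CKO replicates 1 and 2.

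Fixed gene lists passed under a preset correlation between genes, but similar numbers passed when the libraries were split in other ways. Of 46 lists with at least 3 tested members, 15 passed a camera adjusted p of 0.05, 11 lower and 4 higher in Olfm4CKO. The same test passed 19 lists with the libraries split by replicate number and 13 with the remaining split into 2 and 2. The number of calls therefore does not set genotype apart. Between genotypes, 0 lists passed with a correlation estimated for each list (smallest adjusted p = 0.683), and fry called 0 (smallest adjusted p = 0.176). At an unadjusted p below 0.05 there were 2 lists with the estimated correlation and 4 with fry. A higher correlation between genes does not account for every lost call. The branched-chain, tricarboxylic acid cycle and lipolysis lists had estimates of -0.046, -0.023 and -0.061, below the preset 0.01. Their unadjusted camera p still rose from 1.46e-05, 0.000664 and 0.00247 to 0.0422, 0.0665 and 0.0838. The other called lists had estimates above the preset value. When 1 library was left out, 34 of the 46 lists had a median or a test direction that turned in at least 1 fit, and 9 passed as lower in 1 fit and as higher in another. Over all lists, 4 members passed when adjusted over the list alone and 0 over all genes tested.

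**Figure D2:**
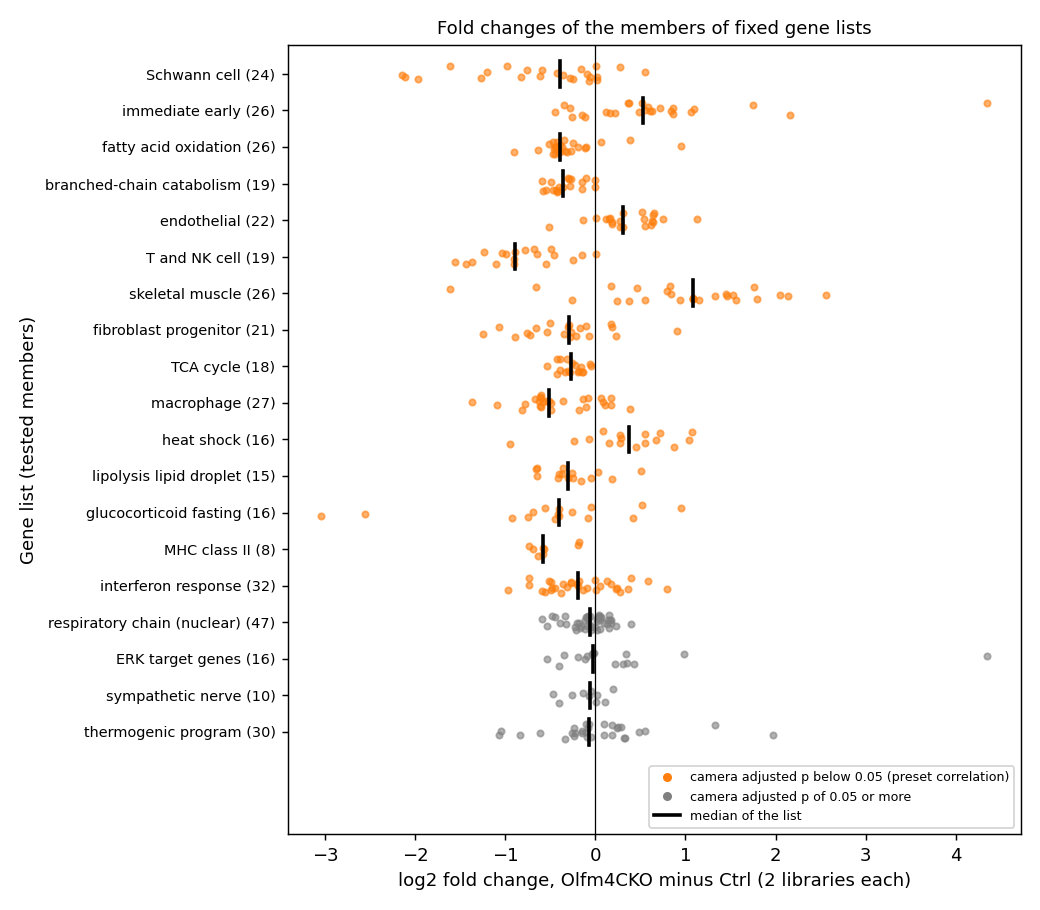
Log2 fold change (Olfm4CKO minus Ctrl, 2 libraries each) of every tested member of the 15 lists past the camera threshold with the preset correlation (orange) and of 4 lists that did not pass (grey), with the number of tested members after each name. Black bars are list medians, from -0.90 for T and NK cells to 1.08 for skeletal muscle, and the point at 4.35 in 2 lists is Fosl1, a fitted value that rests on 1 Ctrl count.

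Markers of Schwann cells, the glia that wrap peripheral axons, passed as a list as lower in Olfm4CKO under the preset correlation. Of 24 tested members 19 lay below 0, with a median log2 fold change of -0.39 (camera adjusted p = 1.47e-07, adjusted p = 0.683 with an estimated correlation). Mbp, myelin basic protein (chromosome 18, 82475091 to 82585637), had 103 ± 0.363 CPM in Ctrl and 43.0 ± 3.03 CPM in Olfm4CKO, a log2 fold change of -1.26 ± 0.33 (SE). Prx, periaxin, had 17.6 ± 12.6 against 4.48 ± 0.767 CPM (-1.97 ± 0.53 SE), and Ncmap, a protein of noncompact myelin, had 3.01 ± 2.04 against 0.673 ± 0.0381 CPM (-2.15 ± 0.73 SE). Without Ctrl replicate 2 these log2 fold changes were -0.94 for Prx and -1.20 for Ncmap, and Prx passed without Ctrl replicate 1 (-2.56, edgeR adjusted p = 0.00170; range over the libraries left out 0.00170 to 1.00). When adjusted over the list alone 3 members passed, Mbp and Prx among them (0.0277 each), and 0 members passed over all genes tested. The lineage factor Sox10 (-0.59 ± 0.58 SE) and S100b (0.02 ± 0.44 SE), which are not tied to myelin, had overlapping groups. S100b lay on the other side of 0 under limma-voom, and Sox10 ran from -1.12 to 0.26 over the libraries left out. S100b is also on the list of secreted factors reported from brown fat. Neither gene therefore shows whether the number of Schwann cells differed. The list passed whichever of the 4 libraries was left out, with medians of -0.88 without Ctrl replicate 1, -0.31 without Ctrl replicate 2 (camera adjusted p = 0.0173), -0.68 without Olfm4CKO replicate 1 and -0.77 without Olfm4CKO replicate 2.

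**Figure D3:**
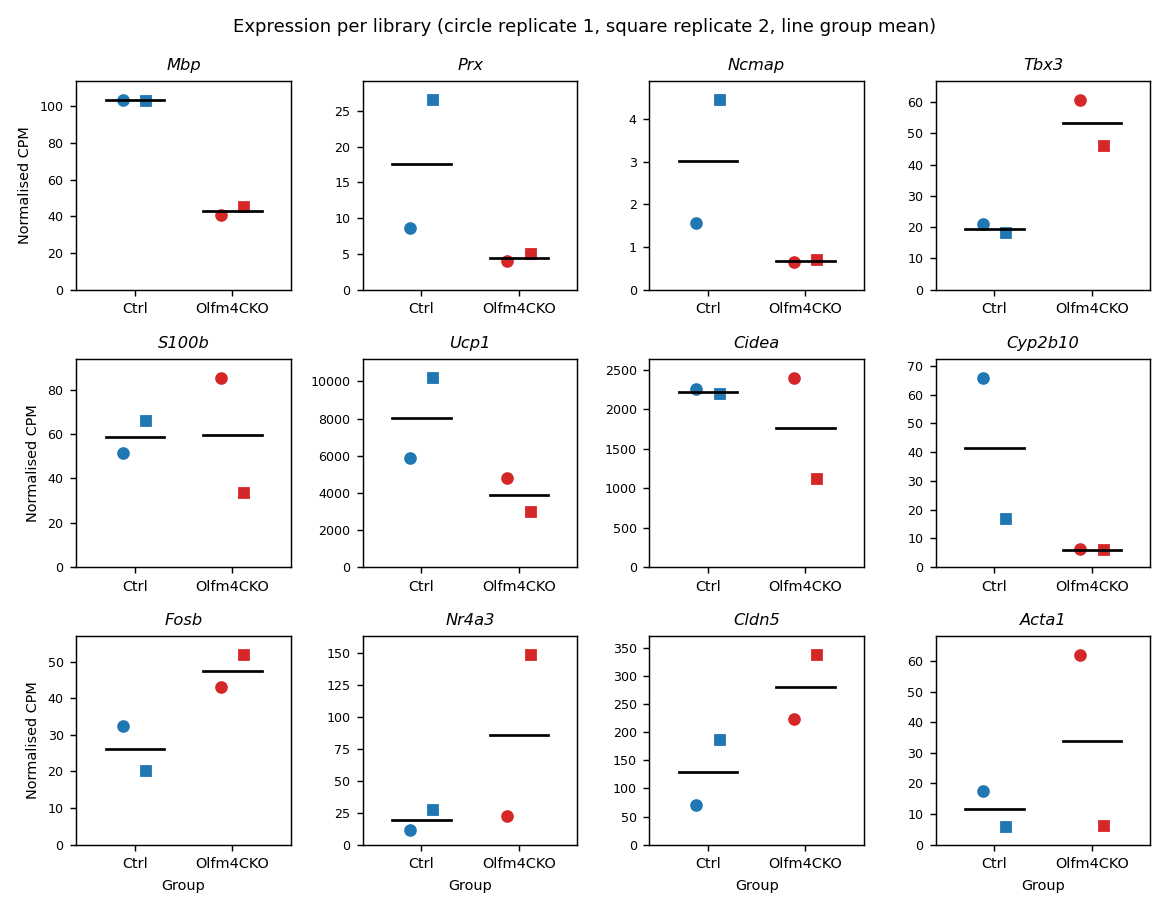
Normalised CPM of 12 genes in each library, with the group on the horizontal axis. Circles are replicate 1, squares replicate 2 and black lines group means; each vertical axis starts at 0. Mbp, Prx and Ncmap lie lower in both Olfm4CKO libraries than in both Ctrl libraries, while Acta1 is high in Olfm4CKO replicate 1 alone.

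Immediate early genes, which cells switch on within minutes of a stimulus, were higher in Olfm4CKO. Of 26 tested members 20 lay above 0, with a median log2 fold change of 0.53 (camera adjusted p = 1.47e-06, adjusted p = 0.683 with an estimated correlation), and 0 members passed by either adjustment. Fosb went from 26.2 ± 8.68 to 47.5 ± 6.15 CPM (0.86 ± 0.36 SE) and Klf4 from 77.9 ± 16.2 to 140 ± 7.85 CPM (0.84 ± 0.34 SE). The nuclear receptor Nr4a3 (2.16 ± 0.72 SE) reached 148 CPM in Olfm4CKO replicate 2 and 22.8 CPM in replicate 1, the latter below the 27.0 CPM of Ctrl replicate 2. Its log2 fold change was 0.25 without Olfm4CKO replicate 2, and it passed without Ctrl replicate 2 (2.96, edgeR adjusted p = 8.40e-04) and without Olfm4CKO replicate 1 (2.97, 3.79e-08; range over the libraries left out 3.79e-08 to 0.998). Fosl1 had 1 count in Ctrl and 24 in Olfm4CKO, a ratio of 25.8 with an exact 95% counting interval of 4.21 to 1060. The median was 0.12 without Olfm4CKO replicate 1 and 0.31 without Olfm4CKO replicate 2, and the call ended without Ctrl replicate 1 (median 0.51, camera adjusted p = 0.0548), the library with Y-linked transcripts. Genes used as readouts of MEK and ERK activity did not pass as a list (16 tested, median -0.02 but mean 0.33, camera adjusted p = 0.187). That mean includes Fosl1, whose fitted log2 fold change of 4.35 rests on 1 Ctrl count. Among these readouts Spry4, a feedback inhibitor of the pathway, had 16.9 ± 0.684 CPM in Ctrl and 33.4 ± 12.1 CPM in Olfm4CKO (0.98 ± 0.36 SE, edgeR adjusted p = 0.9998). The ERK phosphatase Dusp6 had a log2 fold change of -0.02.

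Ucp1, the uncoupling protein that makes heat in brown fat (chromosome 8, 83290348 to 83298456), had 8047 ± 3059 CPM in Ctrl and 3879 ± 1323 CPM in Olfm4CKO. Its log2 fold change of -1.05 ± 0.45 (SE) did not pass (edgeR adjusted p = 0.9998), although both Olfm4CKO libraries lay below both Ctrl libraries. It was -0.60 without Ctrl replicate 2 and ran to -1.43 over the other libraries left out, and passed in none of these fits. The wider thermogenic list did not pass (30 tested, median -0.08, mean 0.02, camera adjusted p = 0.559). Within it the lipid droplet protein Cidea (-0.34 ± 0.44 SE), the deiodinase Dio2 (0.33 ± 0.52 SE), the coactivator Ppargc1a (0.24 ± 0.46 SE) and the elongase Elovl3 (-1.07 ± 0.74 SE) had overlapping groups. The genes beside Ucp1 on the chromosome, Elmod2 and Tbc1d9, had log2 fold changes of 0.77 ± 0.37 and 0.51 ± 0.40 (SE), and the list of these 3 genes did not pass (camera adjusted p = 0.651). The labels leave open whether the Ucp1-driven Cre transgene differs between the groups, so these values can reflect it as well.

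The lists of fatty acid oxidation, branched-chain amino acid breakdown, the tricarboxylic acid cycle and lipolysis passed as lower in Olfm4CKO under the preset correlation. For fatty acid oxidation 23 of 26 members lay below 0, with a median log2 fold change of -0.40 (camera adjusted p = 7.86e-05, adjusted p = 0.683 with an estimated correlation). Etfdh and Etfa, which pass electrons from fatty acid oxidation to the respiratory chain, had 747 ± 29.2 against 482 ± 118 CPM and 1341 ± 101 against 936 ± 91.8 CPM. The hydratase Echs1 had 1037 ± 174 against 747 ± 2.74 CPM and the peroxisomal enzyme Ehhadh 173 ± 59.9 against 92.6 ± 60.9 CPM. All 19 members of branched-chain amino acid breakdown lay below 0 (median -0.36, camera adjusted p = 1.68e-04, adjusted p = 0.683 with an estimated correlation), among them Mccc2 (-0.59 ± 0.33 SE), Pcca (-0.58 ± 0.35 SE), Mut (-0.54 ± 0.36 SE) and Pccb (-0.49 ± 0.36 SE). All 18 members of the tricarboxylic acid cycle lay below 0 (median -0.27, camera adjusted p = 0.00340, adjusted p = 0.683 with an estimated correlation), including Sucla2 (-0.54), Suclg1 (-0.42), Idh3g (-0.40) and Idh3b (-0.39), of which Idh3g was -0.07 and Suclg1 -0.21 without Ctrl replicate 2. Lipolysis and lipid droplet genes had 12 of 15 members below 0 (median -0.30, camera adjusted p = 0.00946, adjusted p = 0.683 with an estimated correlation), with Plin5 at 284 ± 3.32 against 181 ± 23.7 CPM and Hilpda (-0.66), Fitm2 (-0.65) and Plin3 (-0.40) also below 0. Without Olfm4CKO replicate 1 Fitm2 was -0.12 and Plin3 -0.20, and without Olfm4CKO replicate 2 Fitm2 was -1.45 and Plin3 -0.62. No member of these 4 lists passed by either adjustment. The fatty acid oxidation and branched-chain lists passed without each library in turn, with a fatty acid oxidation median of -0.23 without Ctrl replicate 2. The cycle list did not pass without Ctrl replicate 2 (0.133) or Olfm4CKO replicate 1 (0.068), and the lipolysis list passed only without Olfm4CKO replicate 1 (0.0203, median -0.20), not without Ctrl replicate 1 (0.190), Ctrl replicate 2 (0.160, median -0.17) or Olfm4CKO replicate 2 (0.412). Nuclear genes of the respiratory chain did not pass (47 tested, median -0.06, camera adjusted p = 0.13), although they passed as lower without Ctrl replicate 1 (0.00565) or Olfm4CKO replicate 1 (1.81e-10) and as higher without Olfm4CKO replicate 2 (0.00873), and not without Ctrl replicate 2 (0.560). Mitochondrially encoded genes lay the other way, with 11 of 13 above 0 and a median of 0.27, and did not pass (camera adjusted p = 0.13). They passed as higher without Olfm4CKO replicate 2 (median 0.52, 0.00626; range over the libraries left out 0.00626 to 0.879), and the median was -0.03 without Olfm4CKO replicate 1. Their transcripts took 19.01% and 13.68% of counts in Ctrl and 19.17% and 16.9% in Olfm4CKO.

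Vascular endothelial markers were higher in Olfm4CKO. Of 22 members 20 lay above 0, with a median log2 fold change of 0.31 (camera adjusted p = 1.75e-04, adjusted p = 0.757 with an estimated correlation), and 0 passed by either adjustment. The tight junction gene Cldn5 went from 129 ± 82.2 to 280 ± 80.8 CPM (1.12 ± 0.47 SE), Sox17 from 25.9 ± 7.76 to 43.5 ± 5.64 CPM, the VEGF receptor Kdr from 200 ± 29.4 to 313 ± 22.6 CPM, and Cdh5, VE-cadherin, from 266 ± 67.2 to 408 ± 83.5 CPM. Pecam1, a pan-endothelial marker, had 164 ± 20.9 against 198 ± 33.9 CPM (0.27 ± 0.35 SE). The list did not pass without Ctrl replicate 2 (camera adjusted p = 0.073, median 0.34) or Olfm4CKO replicate 1 (0.178, median 0.10), and its median was 0.48 without Ctrl replicate 1.

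Marker lists of T and NK cells, macrophages and MHC class II were lower in Olfm4CKO than in the mean of the controls, and Ctrl replicate 2 held their highest level. T and NK cell genes had 18 of 19 members below 0 (median -0.90, camera adjusted p = 6.07e-04, adjusted p = 0.757 with an estimated correlation), with Cd2 at 0.689 and 6.88 CPM in the Ctrl libraries against 1.29 and 1.27 CPM in Olfm4CKO. Cd3g (-1.43), Gzmb (-0.90) and Il2rb (-0.78) had the same sign. Macrophage genes had 21 of 27 members below 0 (median -0.51, camera adjusted p = 0.00473, adjusted p = 0.757 with an estimated correlation), with C1qb at 28.2 and 65.0 CPM in Ctrl against 28.9 and 29.8 CPM, and Ms4a7 (-1.37), C1qa (-0.62), Cd163 (-0.61) and Adgre1 (-0.49) below 0. MHC class II genes had 8 of 8 members below 0 (median -0.58, camera adjusted p = 0.0207, adjusted p = 0.757 with an estimated correlation), including H2-Ab1 (-0.69), H2-Aa (-0.64), Cd74 (-0.58) and H2-Eb1 (-0.57). Without Ctrl replicate 2 these 3 medians turned to 0.90, 0.48 and 0.31, and the T and NK cell (camera adjusted p = 0.0184) and macrophage (0.0270) lists passed as higher, while MHC class II did not pass (0.160). Without Ctrl replicate 1 the medians were -1.44, -0.99 and -1.12. Without Olfm4CKO replicate 1 the T and NK cell list (0.321, median -0.52) and the macrophage list (0.249, median -0.26) did not pass, and without Olfm4CKO replicate 2 the MHC class II list did not (0.0892). Neutrophil genes had 7 of 11 members above 0 and did not pass (median 0.52, camera adjusted p = 0.0883), and they passed as higher without Ctrl replicate 2 (0.0445) and after the trend with transcript length was removed (0.0239). Over the libraries left out their adjusted p lay between 0.0445 and 0.827. Interferon-stimulated genes had 21 of 32 members below 0 (median -0.20, camera adjusted p = 0.0493, adjusted p = 0.757 with an estimated correlation), with Gbp6 (-0.97), Igtp (-0.74), Iigp1 (-0.56) and Psmb8 (-0.49). Their median turned to 0.39 without Ctrl replicate 1 and to 0.14 without Olfm4CKO replicate 2, and was -0.52 and -0.56 without the other 2 libraries. No member of these 4 lists passed by either adjustment.

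Fibroblast and progenitor markers had 17 of 21 members below 0 (median -0.30, camera adjusted p = 9.84e-04, adjusted p = 0.757 with an estimated correlation). Pi16, a marker of early progenitors, had 13.2 ± 2.89 CPM in Ctrl and 5.53 ± 1.89 CPM in Olfm4CKO, and Bmper (-1.07) and Smoc2 (-0.65) also lay below 0 while Icam1 (0.91) lay above. The list did not pass without Ctrl replicate 2 (0.253, median -0.10) or Olfm4CKO replicate 1 (0.124, median -0.17), and its median was -0.52 without Olfm4CKO replicate 2. Col1a1, the main fibrillar collagen, had a log2 fold change of -0.25 ± 0.51 (SE).

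Skeletal muscle genes were higher in Olfm4CKO, with 23 of 26 members above 0 (median 1.08, camera adjusted p = 6.63e-04, adjusted p = 0.757 with an estimated correlation) and were higher in replicate 1 than in replicate 2 of both groups. With a filter at a mean of 5 CPM the list did not pass (median 0.96, camera adjusted p = 0.203). Acta1, skeletal actin, had 17.4 and 5.69 CPM in Ctrl and 61.9 and 5.98 CPM in Olfm4CKO. Tnnt1 (2.05), Pvalb (2.14) and Ttn (2.56) lay above 0, and myoglobin, Mb, which brown fat also makes, lay below (-1.61 ± 0.43 SE). Without Olfm4CKO replicate 1 the median turned to -0.91 and the list passed as lower (camera adjusted p = 8.46e-06), without Ctrl replicate 2 the list did not pass (0.824, median 0.48), and the median was 2.84 without Ctrl replicate 1 and 1.86 without Olfm4CKO replicate 2.

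Heat shock chaperones had 13 of 16 members above 0 (median 0.37, camera adjusted p = 0.00880, adjusted p = 0.757 with an estimated correlation). Hsph1 had 41.6 and 49.4 CPM in Ctrl against 109 and 58.4 CPM in Olfm4CKO, and Dnaja1 (0.67) and Chordc1 (0.56) were above 0 while Hspb8 was below (-0.95). The list did not pass without Ctrl replicate 1 (0.827, median 0.12) or Olfm4CKO replicate 1 (0.884, median 0.04), and its median was 0.62 without Ctrl replicate 2 and 0.66 without Olfm4CKO replicate 2. Glucocorticoid and fasting genes had 13 of 16 members below 0 (median -0.41, camera adjusted p = 0.0181, adjusted p = 0.757 with an estimated correlation). Fkbp5 and Zbtb16, which glucocorticoids induce, had 120 and 315 CPM in Ctrl replicate 1 against 4.27 and 12.3 CPM in Ctrl replicate 2, and Klf9 (-0.92) and Per1 (0.96) had opposite signs. Without Ctrl replicate 1 the median turned to 0.16, without Olfm4CKO replicate 2 the list did not pass (0.0573), and without Ctrl replicate 2 the median was -0.70. With all 4 libraries, no member of the fibroblast, muscle, heat shock or glucocorticoid lists passed by either adjustment. The log2 fold changes of Fkbp5 and Zbtb16 turned to 0.82 and 1.17 without Ctrl replicate 1.

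Sympathetic nerve transcripts, which reach the depot in axons, did not pass (10 tested, median -0.06, camera adjusted p = 0.465). Th, the rate-limiting enzyme of noradrenaline synthesis, had 0 counts in all 4 libraries, which is not detectable at this depth. The neurotrophic gene Nrg4 (-0.07 ± 0.34 SE) differed by less than the spread between libraries. Genes of white adipocytes did not pass (14 tested, median 0.24, camera adjusted p = 0.605). In that list Cyp2e1 passed when adjusted over the list alone (0.0467). Lep had a log2 fold change of 1.26 ± 0.67 (SE), Adipoq of -0.23 ± 0.37 (SE) and the proliferation gene Mki67 of 0.61 ± 0.47 (SE), each with overlapping groups.

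The libraries differed in ways the genotype labels do not give. Ctrl replicate 1 alone held Y-linked transcripts, with 1300 counts of Ddx3y and 886 of Eif2s3y against 0 in the other 3, and 0 counts of Xist against 835, 3334 and 3259. A term for sex would take out the same library, so the values without Ctrl replicate 1 given above are the comparison among libraries without Y-linked transcripts. The deviation of each library from the mean followed transcript length across genes, with Spearman coefficients of 0.297 and -0.459 in Ctrl and -0.213 and 0.469 in Olfm4CKO replicates 1 and 2. The log2 fold change followed it at 0.214, and genes are not independent replicates.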

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

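The test reported here was chosen after the layout of the table was seen. The replicate 3 columns, which no comparison per gene uses, were compared with each other by row. Of 7108 unnamed rows at 10 CPM or more in either library, 21 were at least 4 times higher in Olfm4CKO replicate 3 than in Ctrl replicate 3, and 28 were at least 4 times higher in Ctrl replicate 3. Together these are 0.689% of the rows. At the same minimum, the share of named genes at least 4 times apart was 0.453% to 0.882% between an Olfm4CKO and a Ctrl library of replicates 1 and 2 (4 pairs), 0.799% between the 2 Ctrl libraries and 1.112% between the 2 Olfm4CKO libraries. The rows have no gene names that can be trusted, and 1 library per group allows no test. The highest row took 20.34% of the counts in Ctrl replicate 3 and 18.27% in Olfm4CKO replicate 3, against 4.94% to 7.26% for the highest gene in the other 4 libraries. No biological explanation was tested.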

How the results depend on the processing

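Alternatives chosen after seeing the data were the filter at a mean of 5 CPM, DESeq2 and its size factors, limma-voom alone, with quantile normalization and with library weights, leaving out mitochondrially encoded genes, and removing the trend with transcript length. The pseudocounts, the filter on mean FPKM of 5 and eBayes without a trend were planned for FPKM and not run, and quantile normalization and library weights were run only within limma-voom. Leaving out replicate 3 was not run because those columns entered no fit. The count of 0 genes stayed at 0 for both other thresholds, both filters, the scaling by totals or DESeq2 size factors, robust empirical Bayes, the 3 limma-voom fits and without mitochondrially encoded genes. DESeq2 called 1 gene, Cyp2b10 (adjusted p = 0.00923), and the count ranged from 6 to 27 without 1 library, where each fit has fewer samples. The cause of the DESeq2 call was not tested. Olfm4 had 0 counts whichever library was left out.

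Across all genes, deviations of same-numbered libraries had r = 0.0027 (Spearman -0.097), over only 2 pairs. Single genes did share a level by replicate number, as the split by that number called 12 genes. Whether the numbers pair the libraries is therefore open. With the replicate block 4 genes passed (Cyp2b10, Erdr1, Xist and a predicted gene) and 15 lists, and the neutrophil list passed as higher (adjusted p = 0.0445).

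For calls lost with the estimated correlation, a higher correlation between genes is not the reason in every list, as given in the results. The cause was not otherwise tested. The count of 15 lists went to 0 with the estimated correlation and to 0 with fry. It was 16 to 19 without 1 library and 10 to 17 under the other alternatives. All 15 kept their direction and call with DESeq2 size factors, library totals, no filter or no mitochondrially encoded genes, 10 kept the call with quantile normalization, and 10, 7, 8 and 11 kept it without Ctrl replicates 1 and 2 and Olfm4CKO replicates 1 and 2. The interferon list lost its call in the most fits, with adjusted p from 0.0514 to 0.0675 in the camera fits with all 4 libraries and the preset correlation where it was lost. Without 1 library, the median changed sign or the test its direction for 34 of the 46 lists. Not described in the results, though past the threshold both as lower and as higher, were B and plasma cells (medians -1.553 to 1.687), cholesterol synthesis (-0.518 to 0.401), de novo lipogenesis (-0.409 to 0.611), extracellular matrix (-0.41 to 0.184) and ribosomal proteins (-0.321 to 0.419). Among the lists described, those that turned were clock genes (-0.216 to 0.332), ERK targets (-0.121 to 0.258), glucocorticoid genes (-0.696 to 0.161), interferon genes (-0.561 to 0.391), macrophages (-0.99 to 0.477), MHC class II (-1.122 to 0.314), mitochondrially encoded genes (-0.034 to 0.518), neutrophils (0.05 to 0.702), nuclear respiratory chain (-0.517 to 0.317), olfactomedin genes (-0.324 to 0.582), skeletal muscle (-0.908 to 2.844), sympathetic nerve (-0.29 to 0.008), T and NK cells (-1.439 to 0.897), the thermogenic program (-0.211 to 0.066, median only) and white adipocytes (-0.106 to 0.427), and the cause was not tested.

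The log2 fold change of S100b reversed to -0.126 with limma-voom, -0.12 with quantile normalization, -0.126 with library weights and -0.123 with the replicate block, and that of Dusp6 to 0.026 with library totals and 0.006 without mitochondrially encoded genes; both lie near 0 and the cause was not tested. Without 1 library, ranges crossed 0 for Acta1 (-0.927 to 2.572), Adgre1 (-1.155 to 0.296), C1qa (-1.076 to 0.058), C1qb (-1.151 to 0.063), Cd2 (-2.419 to 0.897), Cd3g (-2.319 to 1.352), Cd74 (-1.122 to 0.312), Cidea (-0.975 to 0.108), Col1a1 (-1.374 to 0.392), Dio2 (-0.572 to 1.034), Dusp6 (-0.742 to 0.477), Elovl3 (-1.901 to 1.065), Fkbp5 (-3.988 to 0.82), H2-Aa (-1.127 to 0.105), H2-Ab1 (-1.273 to 0.316), H2-Eb1 (-1.07 to 0.2), Il2rb (-1.323 to 0.115), Klf9 (-1.629 to 0.164), Nrg4 (-0.281 to 0.193), Ppargc1a (-0.307 to 1.159), Pvalb (-0.873 to 3.045), S100b (-0.797 to 0.536), Sox10 (-1.122 to 0.264), Ttn (-1.243 to 5.189) and Zbtb16 (-3.494 to 1.171). The cause was not tested. Depth was similar in the 4 libraries, and the limit of a count of 0 was at most 0.195 CPM.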

Other observations

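Chosen after the results were seen were the tests of myelin genes against other Schwann cell genes, of the fastest immediate early genes, of the immediate early list without Ctrl replicate 1, and of other splits for the gene lists. The other tests were written before their values were seen, though counts per library had been looked at.

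The circadian clock list did not pass between genotypes (20 tested, median log2 fold change 0.05, camera adjusted p = 0.49), and its members had different levels in single libraries. Without Olfm4CKO replicate 1 it passed as higher (median 0.33, 0.0328), and over the 4 libraries left out the median lay between -0.22 and 0.33 and the adjusted p between 0.0328 and 0.526. Per2, a core clock repressor, had 261 and 336 counts in the replicate 1 libraries of Ctrl and Olfm4CKO and 53 and 44 in the replicate 2 libraries. When the libraries were split by replicate number instead of genotype, edgeR called 12 genes, 5 of them skeletal muscle genes (Acta1, Ckm, Tnnc2, Tnni2 and Tnnt3). The interferon-induced gene Ifit1 also differed (567 and 433 counts against 119 and 113), as did Lars2 (15763 and 18781 against 3481 and 4164), with Sorl1 and Zbed5 the other way. Within the clock list Per1 had a log2 fold change of 0.96 and Nr1d1 of -1.12 between genotypes, and neither passed.

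Xist, the long noncoding RNA of the inactive X chromosome, had a log2 difference of -2.09 between Ctrl replicate 2 and the mean of the Olfm4CKO libraries. Over the 314 tested genes with a transcript of at least 10000 bases, Xist included, the median of this difference was -0.83. Of the 314, 8 lay at or below the value of Xist, with Xist itself among the 8.

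The 4 libraries make 3 splits into 2 and 2, too few for a share under 0.05. The genotype split gave 0 genes and the highest other 12. All 3 splits reach a count of 0 by construction, so for genes this comparison says nothing. For lists it gave 15 and the highest other 19, so 2 of 3 gave as many. At an unadjusted p below 0.05 the genotype split gave 287 genes, the split by replicate number 814 and the remaining split 1503. So the samples hold structure that genotype does not follow. The remaining split sets Ctrl replicate 1 and Olfm4CKO replicate 2, with positive transcript length coefficients (0.297 and 0.469), against Ctrl replicate 2 and Olfm4CKO replicate 1 (-0.459 and -0.213). Whether the length trend makes that count was not tested.

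The first pattern is the lower Schwann cell list in Olfm4CKO. Without Ctrl replicate 2 the median of the list stayed below 0 (-0.31, camera adjusted p = 0.0173). It was -0.88 without Ctrl replicate 1, the library with Y-linked transcripts (1.52e-10, range over the 4 libraries left out 1.52e-10 to 0.0173). The sign of the median therefore needs neither library. The calls cannot exclude a single library as the cause, since 16 to 19 of the 46 lists passed in such fits. Of the 46, 9 passed as lower in 1 fit and as higher in another. Within the list, the 11 myelin genes had a median of -1.20, all below 0, and the 13 other members of -0.07. The difference was -1.13 (permutation p = 0.00024, 100000 resamples across genes, which are not independent). This division of the list was made after the values were seen, so it supports no cause of its own. For the same reason it cannot decide whether all Schwann cells were lost equally. Among the other members, S100b is also on the list of secreted factors reported from brown fat. Less myelinated nerve trunk in the dissected tissue is not excluded. The list also differed between replicate numbers (median 0.46, camera adjusted p = 0.00818), and it did not pass with the estimated correlation.

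The second pattern is the higher immediate early list. Without Olfm4CKO replicate 2 its median was 0.31 (camera adjusted p = 0.00474, range over the 4 libraries left out 7.78e-10 to 0.0548). The sign of the median therefore does not need that library. The call cannot exclude it as the cause, for the reason given for the first pattern. Without Olfm4CKO replicate 1 the list passed too (5.87e-06), but the median was 0.12 against 0.53. The size of the median thus rests in large part on Olfm4CKO replicate 1. Without Ctrl replicate 1 the call was lost, but the median was 0.51 against 0.53. None of the libraries left holds Y-linked transcripts, so the size of the median does not need the library that does. The comparison then has Ctrl replicate 2 as its lone control, and properties of that library cannot be told apart from genotype. Time or handling before freezing stays open too: the fastest 8 members had a median of 0.30 and the other 18 of 0.66 (exact permutation p = 0.138). A possible explanation is a difference in handling, and the labels give no times.

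The third pattern is the lower fatty acid oxidation and branched-chain lists. Both stayed lower and passed after the trend with transcript length was removed (the larger camera adjusted p was 1.39e-04). Their calls therefore do not need that trend. The same test, at the preset correlation, passed 17 lists after the removal, so it does not decide the cause. Without Ctrl replicate 1, the library with Y-linked transcripts, the medians were -0.45 and -0.38 (the larger camera adjusted p was 0.0298). Their sign therefore does not need that library. The calls cannot exclude it as the cause, for the reason given for the first pattern. Under the other splits neither list passed, with camera adjusted p from 0.465 to 0.89. The 2 lists were picked because they passed between genotypes, so this does not show that they follow genotype. Those splits passed 19 and 13 lists. Neither list passed with the estimated correlation (adjusted p = 0.683 for both), and the genotype itself was tested by no further value.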
